A study of Mus musculus with 51 samples.

How the data were processed

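RNA was measured in 51 libraries of C3H/10T1/2-SAM cells, a mouse mesenchymal line that can form fat cells and that carries the parts of a gene activation system: a catalytically dead Cas9 joined to VP64 and an MS2-P65-HSF1 fusion. A guide RNA directs this system to the promoter of a chosen gene. Per the labels, cells received 250 ng of plasmid with an empty vector (EV), a guide for Pparg (P), or guides for Pparg and Ybx1 together (PY), 48 hours before differentiation began. Rosiglitazone, a drug that activates the PPARG protein, was given at 5 µM from day 0, and RNA was taken at day 0, day 2 and day 4. Libraries were prepared from total RNA with a stranded kit after removal of ribosomal RNA.

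The deposited table gives counts of reads or fragments for 53801 Ensembl genes, with no scaling between libraries. The authors name STAR 2.5.3a, featureCounts 1.5.2, edgeR 3.22.0 and the mouse build mm10 (GRCm38). Their notes do not give the annotation release, the strand setting or the handling of reads that map to several places, so values of genes that overlap on opposite strands and of processed gene copies are uncertain. Identifiers were matched to symbols and positions with GENCODE release M21, which held 53620 of them and lacked 181. The 181 unmatched genes were kept in the tests.

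Total counts ran from 3381870 in PY day 2 replicate 3 to 114566739 in P day 0 replicate 1, with a median of 22.4 M. The libraries fall into 9 groups of transfection and day with 5 or 6 libraries each, from 6 experiments. The labels give each library an experiment number, which differs from the replicate number in the P day 0 and PY day 2 groups. EV has no day 0 library from experiment 6, P none from experiment 2, and PY no day 2 library from experiment 4.

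Levels are CPM, counts scaled to effective library sizes by the cpm function of edgeR, and are given as mean ± SD. Genes with low counts were removed by filterByExpr in edgeR, which kept 17015. Library sizes were scaled by TMM, and 1 quasi-likelihood model (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with a mean for each of the 9 groups gave every comparison. Comparisons were PY with P, P with EV and PY with EV on each day, day 2 and day 4 with day 0 within each transfection, and 3 tests of whether a difference itself changed between days. Tests were two-sided, and genes passed at a Benjamini-Hochberg adjusted p under 0.05 over the 17015 genes. The SE of a log2 fold change was back-calculated from it and its F statistic in the same model. The 95% intervals of fold changes use this SE with a normal quantile and are approximate. The p-values of genes measure the spread between libraries within the 9 groups, where each library of a group comes from a separate experiment. Without a block, libraries of the same experiment in different groups are treated as independent. The p-values of gene lists set the members against the other genes.

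Libraries of the same experiment were checked for shared variation. After removal of the group means, their profiles correlated across genes with a median r of 0.364 over 192 pairs, against -0.0886 over 963 pairs from different experiments. The test fixed beforehand used no block. A fit with the experiment as a replicate block lowered the biological coefficient of variation from 0.325 to 0.202, and its value is given beside a result where it changed the call or moved a count by more than 1.5 times. Both fits were tested on simulated counts of all 51 libraries, with 200 of 17015 genes changed between PY and P of day 4. These counts were drawn from the fit with the experiment block, so they favour that fit. They hold no experiment effects that differ between days. The changed genes had a mean of at least 1 CPM, so the shares do not cover scarcer genes. Without a block the test recovered 29.9% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 87.9% of those changed 3-fold, with 0 false calls. With the block these shares were 59.7%, 88.1% and 97.0%, with 9 false calls beside 40, 59 and 64 genes recovered.

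Before the data were examined, 26 gene lists were fixed. They cover fat cell identity, brown and beige thermogenic genes, mitophagy and autophagy, nuclear-encoded oxidative phosphorylation, mitochondrially encoded messenger RNAs, fatty acid oxidation, fatty acid and triglyceride synthesis, cholesterol synthesis, preadipocyte and fibroblast genes, collagen and extracellular matrix, smooth muscle, skeletal muscle, cartilage and bone, cell cycle, interferon response, inflammatory NF-kB targets, p53 targets, unfolded protein response, heat shock, glycolysis and hypoxia, creatine and calcium cycling, Y-box proteins and partners, cytosolic ribosomal proteins, and markers of macrophages, endothelium and epithelium. Each list was tested against the other genes with camera in limma at a preset correlation between genes of 0.01, adjusted over the lists of each comparison, and again with a correlation estimated from the data. Members that passed are counted over all genes tested and also adjusted over the list alone. In brackets beside a count of members stand the count adjusted over the list alone and the camera adjusted p with an estimated correlation. The fat cell list includes Pparg, which the guides target.

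The rule for named genes was also fixed then. It takes Pparg and Ybx1 everywhere, and the 5 largest rises and falls among passing genes with a mean of at least 1 CPM and the same direction in every experiment. It adds up to 4 passing members of each list, or up to 2 abundant members as values where none passed. It further takes Ucp1, Prdm16, Ppargc1a, Cidea, Cox8b, Pink1, Adipoq, Fabp4 and Cebpa in the PY comparisons, and all genes where 10 or fewer passed. The text gives a part of the genes this rule takes, and results for some genes are not reported here.

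Other settings fixed beforehand were RLE size factors, no filter, a stricter filter (1 CPM in 5 libraries), the experiment block, a fit of the compared groups only, the Wald test of DESeq2 1.42.0, and leaving out each library or each experiment. A block of experiment and day together, and leaving out the 2 libraries with the lowest totals, were chosen after seeing the data. Each count was also set against 100 splits of its libraries, the real one included, drawn so that a set of them parts as many experiment pairs as the labels do. These used the dispersions of the model above. The guide sequences were not used here.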

Results

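RNA of C3H/10T1/2-SAM pre-adipocytes was counted in 51 libraries. Cells carried an empty vector (EV), a guide that activates Pparg (P), or guides that activate Pparg and Ybx1 (PY), and were sampled on days 0, 2 and 4, where the labels place rosiglitazone from day 0. EV had 5, 6 and 6 libraries on the 3 days, P had 5, 6 and 6, and PY had 6, 5 and 6. The lowest total counts were 3381870 in PY day 2 replicate 3 and 4117244 in PY day 0 replicate 3, and the highest was 114566739 in P day 0 replicate 1. The first principal component held 34.5% of the variance, and day accounted for 62.1% of it. Experiment accounted for 65.6% of the second component, which held 14.1%.

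Pparg (ENSMUSG00000000440, GRCm38 chromosome 6, 115360951 to 115490399, plus strand), the nuclear receptor that drives fat cell formation, was 4 to 5 times as high with the Pparg guide as with the empty vector. At day 0 it stood at 242 ± 91.9 CPM in P (SD, n = 5) against 51.5 ± 7.45 in EV (n = 5), a 4.69-fold difference (adjusted p = 0.000141) seen in 4 of 4 experiments. The difference was 5.3-fold at day 2 (adjusted p = 5.22e-07) and 4.18-fold at day 4 (adjusted p = 2.1e-06), in 6 of 6 experiments each. PY cells held Pparg 5.08-fold, 5.28-fold and 4.64-fold above EV on the 3 days. Between PY and P, Pparg differed by log2 0.12 ± 0.29 (SE), -0.01 ± 0.29 and 0.15 ± 0.28, and 95% intervals of the fold ran from 0.732 to 1.61, 0.673 to 1.48 and 0.763 to 1.61. It was higher in PY in 5 of 5, 3 of 5 and 5 of 6 experiments (adjusted p = 1 on each day, with the experiment block too). All 3 values changed sign without some single libraries, and the day 2 value under several other settings too.

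Ybx1 (ENSMUSG00000028639, GRCm38 chromosome 4, 119277981 to 119294604, minus strand), which encodes a Y-box protein that binds RNA and DNA, was about 3 times as high where its guide was added. PY held 2160 ± 604 CPM (n = 6) against 707 ± 99.2 in P (n = 5) at day 0, 3.05-fold more (adjusted p = 2.49e-08). It was 2.95-fold higher at day 2 (adjusted p = 3.41e-08) and 3.24-fold higher at day 4 (1870 ± 404 against 579 ± 72.1 CPM, n = 6 each, adjusted p = 1.02e-09). The direction held in 5 of 5, 5 of 5 and 6 of 6 experiments. Against EV the folds in PY were 3.11, 3.07 and 3.24. The Pparg guide alone left Ybx1 within log2 0.03 ± 0.17, 0.06 ± 0.16 and 0.00 ± 0.16 of EV, with adjusted p of 1, 1 and 0.998. All 3 values turned negative without some single libraries, and those of days 0 and 4 also under other settings.

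**Figure D1:**
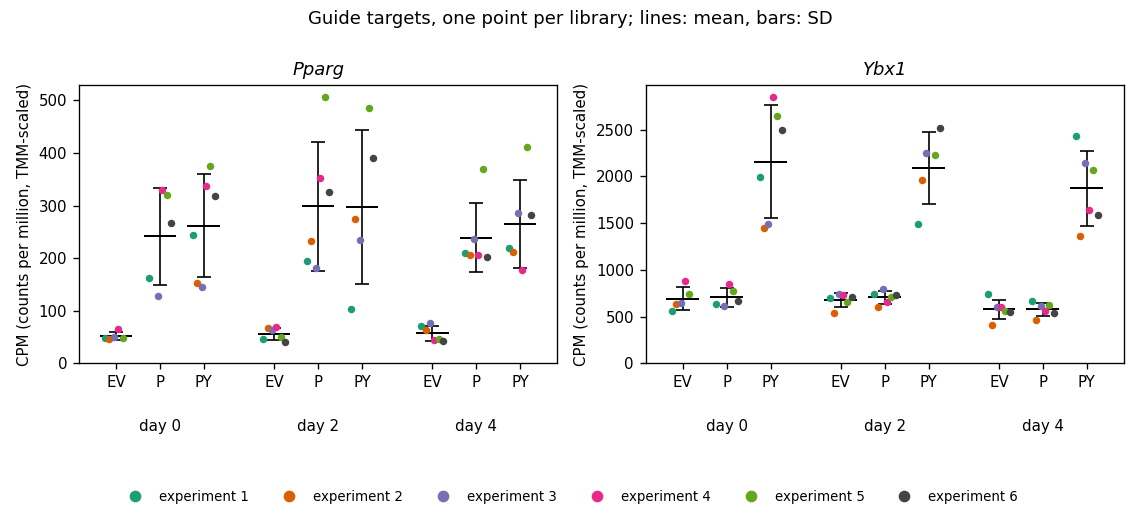
Pparg and Ybx1 in CPM for each library, by transfection and day, with colours for the 6 experiments and bars for the mean ± SD. Pparg was 242 ± 91.9 CPM in P and 51.5 ± 7.45 CPM in EV at day 0, and Ybx1 was 2160 ± 604 CPM in PY and 707 ± 99.2 CPM in P.

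PY was set against P to see what the Ybx1 guide added to the Pparg guide. At day 0, 5 genes passed and all were higher in PY: Ybx1, Jmjd1c, Nlrp2, Ybx1-ps2 and Gm11560. Jmjd1c (ENSMUSG00000037876, chromosome 10, 67096125 to 67256326), of the family of JmjC histone demethylases, was at 500 ± 163 CPM in PY (n = 6) and 183 ± 11.5 in P (n = 5), 2.73-fold higher (adjusted p = 2.49e-08) in 5 of 5 experiments. Nlrp2 (ENSMUSG00000035177, chromosome 7, 5298547 to 5351035), of the NOD-like receptor family, was at 4.16 ± 4.51 and 0.137 ± 0.122 CPM, 29.2-fold higher (log2 4.87 ± 0.78, adjusted p = 0.000728), also in 5 of 5, and 18.1-fold without PY day 0 replicate 4. Ybx1-ps2 (ENSMUSG00000107035) and Gm11560 (ENSMUSG00000086688), processed pseudogenes, were 2.74-fold and 3.42-fold higher. They are 92.5% and 96.1% identical to Ybx1 transcripts over 978 and 932 bases, and how reads that map to several places were counted is not stated. Fabp4, a fatty acid carrier of fat cells, did not pass (1.3-fold, 95% interval 0.421 to 4.04, and lower in PY without PY day 0 replicate 4 or 6), and none of the other genes listed in advance for PY passed either.

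Among the lists at day 0, no member passed over all genes or when adjusted over the list alone. By camera the interferon response list stood higher in PY (29 of 29 members positive, median log2 0.21, adjusted p = 0.00293), as did the epithelial list (adjusted p = 0.00216) and the thermogenic list (adjusted p = 0.0392). With an estimated correlation none of these held (adjusted p = 0.979, adjusted p = 0.276 and adjusted p = 0.979), although the epithelial list gave adjusted p = 0.00028 with the estimated correlation and the experiment block. The 5 genes fell to 3 without PY day 0 replicate 5, to 2 without experiment 1 and to 3 without experiment 4. Ybx1-ps2 and Gm11560 did not pass without P day 0 replicate 1 (adjusted p = 0.0552 and adjusted p = 0.0739) or PY day 0 replicate 5 (adjusted p = 0.0565 each), nor Gm11560 without P day 0 replicate 2 (adjusted p = 0.05), and Nlrp2 did not without experiment 1 (adjusted p = 0.0613). Left out by experiment, Ybx1-ps2 did not pass without 1, 3, 4 or 6 (adjusted p = 0.248, 0.0989, 0.138 and 0.0667), and Gm11560 not without 1, 4 or 5 (adjusted p = 0.259, 0.138 and 0.112). Experiment and day as the block gave 19 genes. A fit of the PY and P libraries of day 0 alone passed 0 genes in edgeR, with Ybx1 at adjusted p = 0.0709. In the full fit 106 genes (0.623%) had an unadjusted p under 0.05, fewer than evenly spread p-values would give. That fit had no block, so this does not exclude further differences.

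On day 2 the PY and P cells differed in 2 genes, Ybx1 and Ybx1-ps2 (2.82-fold, adjusted p = 0.00751), and on day 4 in 3, Ybx1, Ybx1-ps2 (3.27-fold, adjusted p = 0.000217) and Gm11560 (3.19-fold, adjusted p = 0.0169), all higher in PY. At day 4 Gm11560 did not pass without 6 of 12 single libraries (adjusted p up to 0.111) or without experiment 1, 2, 4, 5 or 6. With no filter Ybx1-ps2 at day 2 (adjusted p = 0.0639) and Gm11560 at day 4 (adjusted p = 0.0588) did not pass, nor did either in the compared groups alone (adjusted p = 0.895 and adjusted p = 0.331). Fat cell genes did not pass. Fabp4 was at 3980 ± 1840 CPM in PY and 2710 ± 1330 in P at day 4 (n = 6 each, 1.47-fold, 95% interval 0.501 to 4.3). Cidea, a lipid droplet protein of brown fat, was at 0.503 ± 0.389 and 0.22 ± 0.221 CPM (1.91-fold, 95% interval 0.809 to 4.49, and 2.99-fold without P day 4 replicate 5). Pink1, a kinase that starts mitophagy, differed 0.998-fold (0.717 to 1.39) and changed sign under several settings. Adipoq, Cebpa, Cox8b, Prdm16 and Ppargc1a did not pass on either day. Ucp1, the uncoupling protein of brown fat, had at most 10 counts in any library and was not kept by the filter, so a difference was not detectable at this depth. Gm11560 did not pass at day 2 (log2 1.59, adjusted p = 0.0679), but did with the experiment block (adjusted p = 0.00472), in DESeq2 (adjusted p = 0.00529) and with the stricter filter (adjusted p = 0.0426).

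Nlrp2 and Jmjd1c fall outside the rule on these later days and were chosen after their values were seen. Jmjd1c differed by log2 0.65 at day 2 (adjusted p = 0.284) and 0.50 at day 4 (adjusted p = 1), with PY at 176 to 274 CPM and then 175 to 236 CPM. Nlrp2 differed by log2 3.87 at day 2 (adjusted p = 1, 22.7-fold without P day 2 replicate 5) and 4.33 at day 4 (adjusted p = 0.359, 2.93 without PY day 4 replicate 4) and did not pass, but did at day 2 with the experiment block (adjusted p = 0.0214). With experiment and day as the block Nlrp2 passed at day 2 (adjusted p = 0.0148) and day 4 (log2 4.28, adjusted p = 0.000358), and Jmjd1c at day 2 (log2 0.68, adjusted p = 0.0243). No list had a passing member. By camera at day 2 fatty acid oxidation (25 of 25 positive, median log2 0.23, adjusted p = 0.000108), oxidative phosphorylation (0.000111), mitophagy (0.00337), fat cell identity (0.00378), thermogenic genes (0.0166) and lipid synthesis (0.0321) stood higher in PY. Interferon response (0.00223), cell cycle (0.00378), unfolded protein response (0.0197), collagen (0.0477) and glycolysis (0.0477) stood lower. All 11 had adjusted p = 0.709 with an estimated correlation. At day 4 fatty acid oxidation (25 of 25 positive, adjusted p = 0.00231) and oxidative phosphorylation (adjusted p = 0.0088) were higher, and interferon response (2 of 29 positive, adjusted p = 1.37e-05) and collagen (adjusted p = 0.0323) lower, each with adjusted p = 0.976 with an estimated correlation.

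The day 2 count was 4 with the experiment block, and fell to 1 without P day 2 replicate 6, PY day 2 replicate 2 or PY day 2 replicate 4, and without experiment 2, 3, 4 or 6. The change of the PY to P difference from day 0 to day 2, and from day 0 to day 4, passed for 0 genes in edgeR and for 0 in DESeq2. In edgeR 84 and 62 genes (0.494% and 0.364%) had an unadjusted p under 0.05, fewer than evenly spread p-values would give. With no block in the test, this does not exclude further changes. Jmjd1c changed by log2 -0.95 between day 0 and day 4 (SE 0.208, adjusted p = 0.622). By camera the interferon list moved lower in PY relative to P over both intervals (adjusted p = 1.06e-06 and adjusted p = 3.73e-09), with adjusted p = 0.895 and adjusted p = 0.988 with an estimated correlation.

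P was set against EV to see what Pparg activation did. At day 0 only Pparg passed. An unadjusted p under 0.05 was held by 237 genes (1.39%), and by 825 with the experiment block. Evenly spread p-values would give a share of 0.05. The test without a block leaves the shared variation of an experiment in the spread. A share under 0.05 therefore neither shows nor excludes further differences. Fabp4 was at 136 ± 144 CPM in P and 6.13 ± 5.27 in EV (n = 5 each, 21.5-fold, 95% interval 5.49 to 84.3, adjusted p = 0.277, and 34.1-fold without EV day 0 replicate 4), and higher in 4 of 4 experiments. The size differed: in experiments 1 and 4 it was at 88.3 and 260 CPM in P and 3.76 and 15.3 in EV. In experiments 3 and 5 it was at only 6.49 and 8.85 CPM in P and 1.94 and 4.3 in EV. Experiment 6, at 315 CPM in P, had no EV library. Of 26 fat cell genes 1 passed, and 7 when adjusted over the list alone. By camera fatty acid oxidation (adjusted p = 4.46e-08), fat cell identity (adjusted p = 4.56e-07) and cell cycle (adjusted p = 0.00222) stood higher in P, each at adjusted p = 0.99 with an estimated correlation. DESeq2 passed 4 genes, Fabp4 among them.

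By day 2, fat cell genes were far higher in P than in EV. Fabp4 reached 2610 ± 1150 CPM against 77.1 ± 59.5 (n = 6 each, 33.8-fold, adjusted p = 0.000391), and Adipoq, the hormone adiponectin, 319 ± 365 against 3.19 ± 2.3 (99.1-fold, adjusted p = 8.78e-06). Cidec and Plin1, which coat lipid droplets, were 485-fold and 348-fold higher, Cebpa, a transcription factor of fat cells, 10.3-fold, the lipase Lipe 31.0-fold and Acsl1, which activates fatty acids, 20.3-fold. In all, 481 genes passed, 471 higher and 10 lower. Of the fat cell list 20 of 26 rose, and 22 when adjusted over the list alone (camera adjusted p = 0.000678 with an estimated correlation). Thermogenic genes rose in 7 of 22 (11 adjusted over the list alone), with Kcnk3, a potassium channel, 78.7-fold and Prdm16, a brown fat regulator, 10.9-fold higher (adjusted p = 0.0381 with an estimated correlation, 0.0834 with the block as well).

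Fatty acid oxidation genes rose at day 2 in 17 of 25 (24 adjusted over the list alone), among them Decr1 2.6-fold and Hadh 2.39-fold (adjusted p = 0.0107 with an estimated correlation, 0.0666 with the block as well). Lipid synthesis genes rose in 8 of 20 (12 adjusted over the list alone), with Agpat2 13.9-fold and Dgat2 7.88-fold, at adjusted p = 0.0381 with an estimated correlation (0.0917 with the block as well). Oxidative phosphorylation genes rose in 9 of 41 (32 adjusted over the list alone), with Cycs, cytochrome c, 2.68-fold and Cyc1 1.87-fold higher, and adjusted p = 0.0869 with an estimated correlation. Of 22 cholesterol synthesis genes 0 passed (camera adjusted p = 0.000139, adjusted p = 0.951 with an estimated correlation), and of 7 mitochondrially encoded messenger RNAs 0 (adjusted p = 0.0336, then adjusted p = 0.951 with an estimated correlation). The collagens Col15a1 and Col6a3 rose 5.81-fold and 2.81-fold, and the mitophagy receptor Bnip3 2.36-fold. Fibrillin 1 (Fbn1) was 1.53-fold lower, Ifit1bl1 4.99-fold, Slpi, a protease inhibitor, 2.51-fold and Pear1 1.49-fold. The experiment block gave 941 genes, 795 higher and 146 lower. The count was 249 without P day 2 replicate 5, where Adipoq was 55.7-fold, Cidec 301-fold, Dgat2 4.91-fold and Kcnk3 39.6-fold higher and Bnip3 and Cyc1 did not pass. Kcnk3 was 123-fold higher without EV day 2 replicate 6. The count was 171 without experiment 5, where the 4 falls, Prdm16, Cycs, Cyc1, Col15a1, Col6a3 and Bnip3 did not pass, and 251 without experiment 6, where the 4 falls, Cyc1, Col6a3 and Bnip3 did not. The falls also did not pass with no filter or without experiment 1 or 2, nor Fbn1 without experiment 4, Ifit1bl1 without 3 and Pear1 without 3 or 4, or without 8, 9, 10 and 6 of 12 single libraries in turn (Fbn1, Ifit1bl1, Slpi and Pear1). In the compared groups alone Fbn1, Pear1 and Bnip3 did not pass, and without the 2 libraries of lowest totals Pear1 did not.

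**Figure D2:**
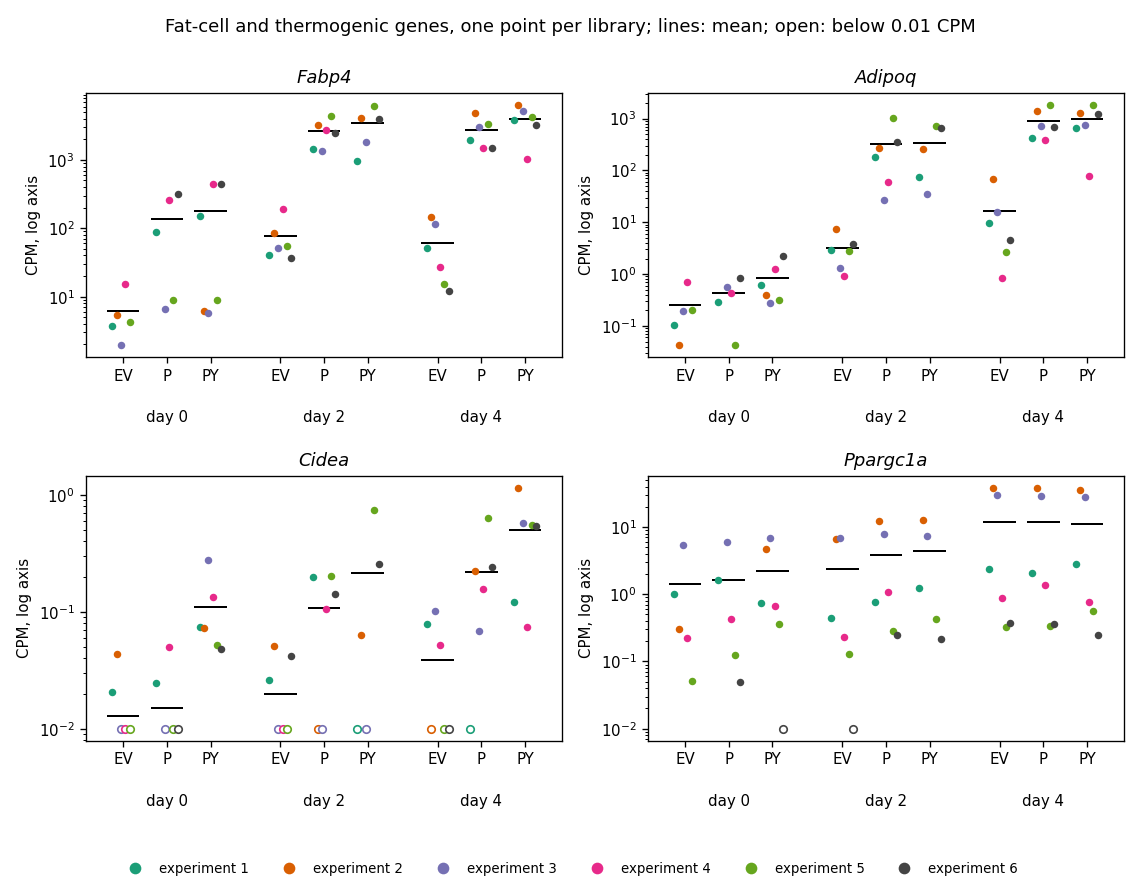
Fabp4, Adipoq, Cidea and Ppargc1a in CPM on a log axis for each library, by transfection and day; lines mark the mean and open points lie below 0.01 CPM. Adipoq stood at 916 ± 592 CPM in P and 16.8 ± 25.4 CPM in EV at day 4, while on that day Ppargc1a was 27.6 to 38.2 CPM in experiments 2 and 3 and at most 2.81 CPM in the others whatever the guide.

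At day 4, 914 genes differed between P and EV, 881 higher in P and 33 lower. The adipokine Cfd was 369-fold higher, the adrenergic receptor Adrb3 193-fold, Tmem182 183-fold, Fabp4 44.2-fold (2710 ± 1330 against 61.4 ± 56.8 CPM, n = 6 each), Adipoq 54.1-fold (916 ± 592 against 16.8 ± 25.4) and Cebpa 6.2-fold. EV day 4 replicate 2 held Adipoq at 67.4 CPM and the other EV libraries 0.834 to 15.8, and without it the folds were 141 for Adipoq, 2470 for Kcnk3, 53.4 for Cox8b and 12.2 for Prdm16. Cfd was 799-fold higher without EV day 4 replicate 6, and Adrb3 113-fold without P day 4 replicate 5. Of the fat cell list 21 of 26 rose (24 adjusted over the list alone, adjusted p = 0.00093 with an estimated correlation), with Acsl1 28.9-fold and Lipe 25.8-fold. Thermogenic genes rose in 9 of 22 (12 adjusted over the list alone), with Kcnk3 155-fold, the respiratory subunit Cox8b 24.6-fold and Prdm16 7.06-fold (camera adjusted p = 2.33e-07, adjusted p = 0.0572 with an estimated correlation). Cidea was at 0.22 ± 0.221 against 0.0388 ± 0.0453 CPM (6.45-fold, adjusted p = 0.0605, adjusted p = 0.0461 with the experiment block, and adjusted p = 0.0471, adjusted p = 0.0245 and adjusted p = 0.0486 without EV replicate 1, P replicate 1 and P replicate 3; 4.16-fold without P replicate 5). Oxidative phosphorylation genes rose in 38 of 41 (40 adjusted over the list alone, adjusted p = 0.00992 with an estimated correlation), with Uqcrfs1 2.45-fold and Cyc1 2.38-fold.

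Fatty acid oxidation genes rose in 20 of 25 at day 4 (23 adjusted over the list alone, adjusted p = 0.00992 with an estimated correlation), with Ehhadh 17.3-fold and Cpt2 2.92-fold. Lipid synthesis genes rose in 16 of 20, the same number adjusted over the list alone (adjusted p = 0.00591 with an estimated correlation), with Agpat2 20.5-fold and Fasn 4.26-fold. Cholesterol synthesis genes rose in 9 of 22 (11 adjusted over the list alone, adjusted p = 0.146 with an estimated correlation), with Insig1 2.85-fold and Acat2 2.43-fold. Of 27 mitophagy genes 2 rose, also 2 adjusted over the list alone, Bnip3 2.57-fold and the mitofusin Mfn2 1.52-fold (camera adjusted p = 0.00865, adjusted p = 0.339 with an estimated correlation), and Pink1 did not pass (1.31-fold, adjusted p = 0.582), but did with the block of experiment and day (adjusted p = 0.0111). The 30 cell cycle genes stood lower as a list with 0 passing (adjusted p = 0.00151, adjusted p = 0.966 with an estimated correlation). Slc6a17 was 1.88-fold lower, Fam189b 1.82-fold and the prolyl hydroxylase subunit P4ha2 1.39-fold. With the block by experiment 1717 genes passed, 1343 higher and 374 lower. Leaving out experiment 2 gave 534, and leaving out experiment 5 gave 594, where the named falls, Mfn2, Insig1 and Acat2 did not pass. Of these 6 genes only Slc6a17 passed without experiment 2. The 3 falls also did not pass without experiment 1 or 6 or with no filter, nor Fam189b and P4ha2 without experiment 3, nor P4ha2 without the 2 libraries of lowest totals, and of the 6 genes only Mfn2 passed in the compared groups alone. Slc6a17, Fam189b, P4ha2, Mfn2 and Insig1 did not pass without 3, 7, 8, 4 and 1 of 12 single libraries.

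PY was set against EV to see the effect of both guides together. At day 0, 8 genes passed, all higher in PY: Ybx1, Pparg, Jmjd1c (2.68-fold), Nlrp2 (43.5-fold), Ybx1-ps2 (3.43-fold), Fabp4, Ubd and Hsd17b4. Fabp4 was at 176 ± 215 CPM (n = 6) against 6.13 ± 5.27 (n = 5), 28.1-fold higher (adjusted p = 0.0441). In experiments 1 and 4 it was at 150 and 438 CPM in PY and 3.76 and 15.3 in EV. In experiments 2, 3 and 5 it was at only 6.24, 5.84 and 8.94 CPM in PY and 5.37, 1.94 and 4.3 in EV. Ubd, a ubiquitin-like protein, was at 8.86 ± 8.17 against 0.934 ± 0.515 CPM (10.7-fold, adjusted p = 0.0366), and Hsd17b4, a peroxisomal enzyme of fatty acid breakdown, at 125 ± 50.1 against 53.2 ± 3.73 CPM (2.35-fold, adjusted p = 0.00432), each higher in 5 of 5 experiments. Fabp4 did not pass when any 1 experiment was left out (adjusted p from 0.104 to 0.756) or without 7 of 11 single libraries (adjusted p up to 0.273), and was 44.5-fold higher without EV day 0 replicate 4. Ubd did not pass without 6 of 11 libraries (adjusted p up to 0.264), and was 6.75-fold higher without PY day 0 replicate 6, and Nlrp2 was 27.0-fold higher without PY day 0 replicate 4. Ubd also did not pass without experiment 1, 2, 3, 5 or 6, and Hsd17b4 did not without experiment 1 (adjusted p = 0.126). With no filter Fabp4 and Ubd did not pass (adjusted p = 0.105 and adjusted p = 0.0716). DESeq2 passed 21 genes, the experiment block 24, the day 0 libraries of PY and EV alone 1, and leaving out experiment 1 gave 5.

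Of 26 fat cell genes 2 passed at day 0, and 8 when adjusted over the list alone (camera adjusted p = 3.06e-10, adjusted p = 0.466 with an estimated correlation). Thermogenic genes (adjusted p = 0.000317), fatty acid oxidation (4.54e-08) and cell cycle (0.0193) stood higher in PY as lists, at adjusted p = 0.466, 0.719 and 0.954 with an estimated correlation. The epithelial markers also stood higher (adjusted p = 7.84e-06, adjusted p = 0.0467 with an estimated correlation), with 0 of 6 passing over all genes and 2 adjusted over the list alone, the keratins Krt8 and Krt18. Without a block Krt8 was higher by log2 4.015, and by log2 5.067 without EV day 0 replicate 4, and did not pass over all genes in either case. Krt8 passed over all genes with the experiment block (log2 4.47, adjusted p = 0.00301), and both did with the block of experiment and day (adjusted p = 0.00115 and adjusted p = 0.0041).

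On day 2, 806 genes differed between PY and EV, 740 higher and 66 lower. Fabp4 was 44.3-fold higher (3420 ± 2090 CPM, n = 5, against 77.1 ± 59.5, n = 6), Adipoq 108-fold, Cidec 691-fold, Plin1 425-fold, Cebpa 13.8-fold, Kcnk3 129-fold, Prdm16 12.2-fold and Cidea 9.9-fold (adjusted p = 0.0188). Fat cell genes rose in 23 of 26 (24 adjusted over the list alone, adjusted p = 0.00391 with an estimated correlation), fatty acid oxidation genes in 21 of 25 (24, adjusted p = 0.0182, and 0.086 with the block as well) and thermogenic genes in 9 of 22 (12, adjusted p = 0.0472, and 0.086 with the block as well). Oxidative phosphorylation genes rose in 20 of 41 (37 adjusted over the list alone, adjusted p = 0.0905 with an estimated correlation), lipid synthesis genes in 10 of 20 (13, adjusted p = 0.0585) and mitophagy genes in 2 of 27 (4, adjusted p = 0.305), the receptors Bnip3 2.8-fold and Bnip3l 1.43-fold. Lower in PY were the integrin Itga5 2.22-fold, the calcium channel Itpr3 1.99-fold, Fbn1 1.62-fold and the growth factor receptor Pdgfrb 1.46-fold. With the experiment block 1739 genes passed, 1159 higher and 580 lower. The count was 392 without PY day 2 replicate 4, where Kcnk3 was 81.0-fold higher and Cidea 3.85-fold, which did not pass. Cidea also did not pass without EV day 2 replicate 1 (adjusted p = 0.0505) or experiment 6 (adjusted p = 0.0942), or in the compared groups alone (adjusted p = 0.0918), and Kcnk3 was 203-fold higher without EV day 2 replicate 6. Without experiment 5 and with the stricter filter Cidea was removed as a low-count gene and not tested. The count was 339 without experiment 5 and 342 without experiment 6. The 4 falls did not pass without experiment 2, 5 or 6, nor Fbn1, Itga5 and Itpr3 without 1 and Itga5 without 4, or without 5, 6, 3 and 2 of 11 single libraries in turn (Itga5, Itpr3, Fbn1 and Pdgfrb). Itga5 and Itpr3 did not pass with no filter, nor Itga5 and Pdgfrb in the compared groups alone.

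On day 4 there were 1333 such genes, 1197 higher in PY and 136 lower. Cfd was 546-fold higher, Fabp4 64.9-fold (3980 ± 1840 CPM, n = 6), Adipoq 57.2-fold (969 ± 605), Cebpa 6.98-fold, Kcnk3 207-fold, Cox8b 26.7-fold, Prdm16 7.28-fold and Cidea 12.3-fold (0.503 ± 0.389 against 0.0388 ± 0.0453 CPM, adjusted p = 0.00213). Cidea was removed as a low-count gene, and so not tested, without experiment 5 and with the stricter filter. Fat cell genes rose in 23 of 26 (24 adjusted over the list alone, adjusted p = 0.00268 with an estimated correlation), oxidative phosphorylation genes in 39 of 41 (40, adjusted p = 0.0101), with Cycs 4-fold, fatty acid oxidation genes in 24 of 25 (24, adjusted p = 0.0101, and 0.0522 with the block as well), with Ehhadh 23.4-fold, and lipid synthesis genes in 16 of 20 (17, adjusted p = 0.0101), with Fasn 4.74-fold. Thermogenic genes rose in 12 of 22 (14 adjusted over the list alone, adjusted p = 0.0819 with an estimated correlation), cholesterol synthesis genes in 11 of 22 (12, adjusted p = 0.222) and mitophagy genes in 4 of 27 (5, adjusted p = 0.245), with Bnip3 2.7-fold, Mfn2 1.68-fold and Phb2 1.47-fold. Pink1 and Ppargc1a did not pass against EV on this day. The chaperone Hspd1 was 2.43-fold higher, and the proteoglycan Bgn 1.65-fold, Pdgfrb 1.42-fold and Sertad4 1.9-fold lower. Blocking by experiment gave 2679 genes, 1740 higher and 939 lower. Without the block, Pdgfrb, Sertad4 and Phb2 did not pass without experiment 5 or 6, nor Pdgfrb without 2 or 3, Sertad4 without 3 or 4 and Phb2 without 1 or 2, or without 2, 6 and 5 of 12 single libraries in turn. Pdgfrb and Sertad4 did not pass with no filter, nor Bgn (adjusted p = 0.0626) and Sertad4 in the compared groups alone. Without EV day 4 replicate 2 the folds were 149 for Adipoq, 3310 for Kcnk3, 58.0 for Cox8b and 12.6 for Prdm16, and Cfd was 1180-fold higher without EV day 4 replicate 6 and 319-fold without PY day 4 replicate 6.

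The P to EV difference itself grew from day 0 to day 4 for 52 genes. In log2 the growth was 8.88 ± 1.99 (SE) for Cfd, 6.23 ± 1.16 for Gpd1, which makes glycerol phosphate, 4.69 ± 0.75 for Acsl1, 3.80 ± 0.69 for Agpat2, 3.63 ± 0.79 for Lipe, 2.26 ± 0.53 for Dgat1, which completes triglycerides, and 1.26 ± 0.30 for Uqcrfs1. Fat cell genes grew in 5 of 26 (11 adjusted over the list alone, adjusted p = 0.0451 with an estimated correlation), lipid synthesis genes in 3 of 20 (15, adjusted p = 0.0248) and oxidative phosphorylation genes in 1 of 41 (38, adjusted p = 0.0248), each at adjusted p = 0.0533 with the block as well. DESeq2 gave 190 genes, the experiment block 207 (199 that grew and 8 that shrank), and the compared groups alone 158. The count was 28 without EV day 0 replicate 1, 19 without replicate 4, 32 without replicate 5, 27 without EV day 4 replicate 6, 17, 25 and 30 without P day 0 replicates 1, 2 and 4, and 90, 19, 129, 33 and 95 without P day 4 replicates 1, 2, 4, 5 and 6. Without experiments 1 to 6 in turn it was 0, 5, 7, 110, 5 and 14. Of 22 single libraries left out in turn, 7 ended the call of Cfd, 7 that of Lipe, 15 that of Dgat1 and 15 that of Uqcrfs1, and these 4 did not pass with no filter either. The growth of Cfd was log2 10.00 without EV day 4 replicate 6, that of Gpd1 7.10 without EV day 4 replicate 2 and 6.95 without P day 0 replicate 5, and that of Lipe 4.34 without P day 0 replicate 5. Acsl1 did not pass without experiment 1, and each of the other 6 genes did not without 3 or more experiments.

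**Figure D3:**
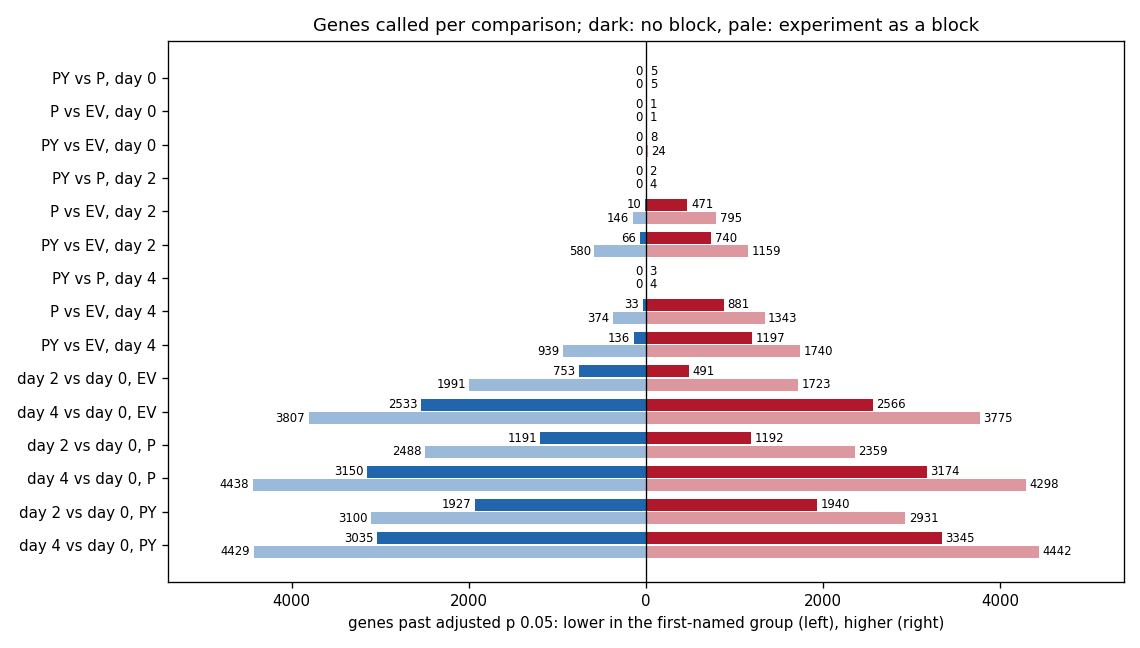
Genes higher and lower in each of 15 comparisons, as bars from 0, dark without a block and pale with the experiment block. Differences between PY and P numbered 5, 2 and 3 genes on the 3 days, and those between PY and EV 8, 806 and 1333.

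Days were compared within each transfection. Later days also lay further from transfection and, by the labels, followed more time on rosiglitazone. Effects of differentiation, the drug and time since transfection therefore cannot be told apart here. In EV cells 491 genes rose and 753 fell from day 0 to day 2. Fabp4 rose 12.2-fold, Adipoq 12.5-fold and the fatty acid transporter Cd36 27.1-fold. Cell cycle genes rose in 15 of 30 (20 adjusted over the list alone, adjusted p = 0.413 with an estimated correlation), with Plk1 2.42-fold, Kif11 2.27-fold and Top2a 2.2-fold. Interferon response genes fell in 16 of 29 (22, adjusted p = 0.413), with Cxcl10 6.0-fold and Ifit2 4.4-fold lower, and NF-kB targets fell in 9 of 19 (12, adjusted p = 0.00863), with Cxcl1 4.89-fold and Nfkbia 2.58-fold lower. Unfolded protein response genes fell in 4 of 22 (7, adjusted p = 0.62), with Atf3 4.95-fold lower, p53 targets in 4 of 20 (5, adjusted p = 0.62), with Mdm2 2.04-fold lower, and collagen genes rose in 4 of 29 (6, adjusted p = 0.62), with Col6a2 2.13-fold. The keratin Krt16 was 20.7-fold and the chemokine Ccl4 9.43-fold lower. Blocking by experiment gave 3714 genes. Without EV day 0 replicates 2, 4 and 5 the count was 782, 794 and 696, without EV day 2 replicates 1 and 2 it was 771 and 821, and without experiments 1, 2, 5 and 6 it was 446, 394, 404 and 824; Fabp4, Adipoq, Cd36, Plk1, Top2a, Cxcl10, Atf3, Col6a2 and Ccl4 each failed to pass without 1 or more experiments, and Fabp4, Adipoq, Cd36 and Atf3 with no filter. Adipoq, Cd36, Col6a2, Atf3 and Ccl4 did not pass without 7, 4, 2, 1 and 1 of 11 single libraries. Without EV day 0 replicate 4 Adipoq was 26.6-fold and Fabp4 19.4-fold higher and Atf3 3.23-fold lower, without EV day 2 replicate 4 Krt16 was 34.1-fold and Ccl4 17.4-fold lower, and without EV day 2 replicate 2 Cd36 was higher by log2 4.17.

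By day 4, 2566 genes had risen and 2533 had fallen in EV cells. Adipoq was 65.9-fold and Cd36 54.3-fold higher, Pi16, a fibroblast gene, 13.3-fold, Zfp423, a factor of preadipocytes, 5.09-fold, Col6a2 3.48-fold and Pink1 2.1-fold. Fat cell genes rose in 10 of 26 and fell in 1 (12 and 1 adjusted over the list alone, camera adjusted p = 0.0511). The interferon gene Ifnb1 was 32.1-fold lower, Cxcl10 12.3-fold, the chemokine Ccl2 8.01-fold, the cystine transporter Slc7a11 6.42-fold, the autophagy receptor Sqstm1 3.05-fold and Mdm2 2.73-fold. Interferon response genes fell in 18 of 29 (21 adjusted over the list alone, adjusted p = 0.548 with an estimated correlation), unfolded protein response genes in 10 of 22 (12, adjusted p = 0.548) and heat shock genes in 8 of 17 (10, adjusted p = 0.548). NF-kB targets fell in 13 of 19 (also 13, adjusted p = 0.0396, and 0.122 with the block as well), and Y-box proteins and partners in 6 of 19 (also 6, adjusted p = 0.548). Leaving out experiment 5 gave 3161 genes. Without EV day 4 replicate 2 Adipoq was 25.1-fold and Cd36 24.3-fold higher. Without EV day 0 replicate 4 Adipoq was 140-fold higher and Ifnb1 18.9-fold lower, and without EV day 0 replicate 1 Pi16 was 29.2-fold higher.

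P and PY cells were compared between days in the same way. Adipoq was scarce at day 0, at 0.0421 to 0.855 CPM in P and 0.278 to 2.22 CPM in PY. Its folds over day 0 rest on these levels and do not compare P with PY. From day 0 to day 2, 1192 genes rose and 1191 fell in P, with Adipoq 779-fold higher (437-fold without P day 2 replicate 5), and 1940 rose and 1927 fell in PY, with Adipoq 385-fold higher. Fat cell genes rose in 21 of 26 in P (also 21 adjusted over the list alone, adjusted p = 0.0926 with an estimated correlation) and in 21 in PY (22, adjusted p = 0.158). Interferon response genes fell in 15 of 29 in P (23, adjusted p = 0.328) and 23 in PY (27, adjusted p = 0.184), and NF-kB targets in 11 of 19 (12, adjusted p = 0.018) and 12 (13, adjusted p = 0.0349, and 0.0596 with the block as well). The experiment block gave 4847 genes in P and 6031 in PY. The P count was 1548 without P day 0 replicate 4, 1536 without P day 2 replicate 5, and 1435, 789 and 1286 without experiments 1, 5 and 6, and the PY count was 1952 without experiment 5.

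By day 4, 3174 genes had risen and 3150 fallen in P, and 3345 and 3035 in PY. The Adipoq folds again rest on scarce day 0 levels and do not compare P with PY. Adipoq was 2240-fold higher in P and 1080-fold in PY, Cfd 1020-fold and 1540-fold (899-fold without PY day 4 replicate 6), the carbonic anhydrase Car3 1150-fold and 1360-fold, Hadh 4.72-fold and 5.2-fold, Pink1 2.98-fold and 2.7-fold, and Sdha, of respiratory complex II, 2.55-fold and 2.82-fold. Oxidative phosphorylation genes rose in 40 of 41 in both (41 adjusted over the list alone, adjusted p = 0.233 in P and adjusted p = 0.145 in PY with an estimated correlation). Mitochondrially encoded messenger RNAs rose in 4 of 7 in P and 7 of 7 in PY (7 each adjusted over the list alone, camera adjusted p = 0.0872 and 0.0143, adjusted p = 0.651 and adjusted p = 0.566 with an estimated correlation), with mt-Cytb 4.29-fold and mt-Co1 2.44-fold higher in PY. Interferon response genes fell in 21 of 29 in P (23, adjusted p = 0.478) and 27 in PY (also 27, adjusted p = 0.234), with Ifnb1 36.0-fold lower in P (59.0-fold without P day 4 replicate 4) and Ifit2 15.7-fold lower in PY. The replication gene Mcm6 was 1.77-fold and 1.9-fold lower, Tpx2, of the mitotic spindle, 2.02-fold lower in P, and Sqstm1 2.62-fold lower in PY. In P, Mcm6 and Tpx2 did not pass without experiment 5 (adjusted p = 0.0658 and adjusted p = 0.0668). NF-kB targets fell in 14 of 19 in P (16, adjusted p = 0.05) and 13 in PY (13, adjusted p = 0.034), which became adjusted p = 0.171 and adjusted p = 0.121 with the block as well.

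The other lists held few passing members in the 9 guide comparisons. Smooth muscle (14 tested), cytosolic ribosomal proteins (53), macrophage (5) and endothelial markers (7) had 0 over all genes in edgeR and 0 adjusted over the list alone. At day 4 P passed 1 of 7 skeletal muscle genes, Des, 1 of 14 cartilage and bone genes and 1 of 8 creatine and calcium genes, both Alpl, which stands in the pair of lists, and 1 of 19 Y-box partners, Ybx2, all higher than in EV, with the same counts when adjusted over each list alone. Glycolysis and hypoxia genes passed for 1 higher and 1 lower of 18, heat shock genes for 1 of 17 and unfolded protein response genes for 1 of 22. Of 23 preadipocyte and fibroblast genes 1, Pdgfrb, fell in PY at day 4 (camera adjusted p = 0.0299, adjusted p = 0.222 with an estimated correlation).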

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

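The tests of the Ybx1 copies, of Nlrp2 and Jmjd1c, and of Fabp4 at day 0 were chosen only after those results were seen.

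At day 0, Fabp4 in P and PY differed widely between experiments. It was 260 and 438 CPM in experiment 4 and 315 and 450 CPM in experiment 6, but 8.85 and 8.94 CPM in experiment 5. The Pparg mRNA level does not account for this, since experiments 5 and 6 held Pparg within 1.5-fold of each other in both P and PY while Fabp4 differed by at least 35.6-fold. Day 2 libraries under a day 0 label are also argued against, since the highest Adipoq level at day 0 was 0.0823 times the lowest at day 2 (2.22 against 27.0 CPM in P and PY). A difference in culture or drug timing between experiments stays open and was not tested.

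Ybx1-ps2 and Gm11560 were higher with the Ybx1 guide, as was Ybx1. Over the 3 days each copy followed the Ybx1 log2 change to within 0.499 combined SE, which is consistent with reads of Ybx1 being assigned to its copies. All libraries together held 1418272 counts of Ybx1 and 2495 of Ybx1-ps2. Activation of the copies themselves stays open, since the strand and multiple mapping settings are not stated.

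Nlrp2 and Jmjd1c were higher at day 0 where the Ybx1 guide was added. Reads shared with Ybx1 are argued against, since the longest stretch of 50 or more bases at 90 percent identity in either gene was 0 bases. A response that follows the Ybx1 mRNA level on each day stays open: the PY to P difference of Jmjd1c changed by -4.57 SE from day 0 to day 4 and that of Nlrp2 by -0.213 SE, but Jmjd1c was picked for its day 0 difference and its change had adjusted p = 0.622 over all genes. A hypothesis also left open is that the guide or plasmid acts on these genes apart from Ybx1, or, for Jmjd1c, that an early response fades. Nlrp2 passed on later days too with the block of experiment and day (adjusted p = 0.000358 at day 4).

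The P to EV difference changed from day 0 to day 4 by a direct test for 52 genes. In log2 the change was 8.88 for Cfd, 4.69 for Acsl1, 6.23 for Gpd1, 3.63 for Lipe, 1.26 for Uqcrfs1, 3.80 for Agpat2 and 2.26 for Dgat1.

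Single libraries stood apart from the rest of their group in 15 of 72 groups of values (20.8%) by Dixon's 95% criterion. Chance gives about 1 in 20 for independent normal values; here values are not logged and 1 library can count for several genes, so that rate is approximate. EV day 0 replicate 4 held Adipoq at 0.705 CPM (others 0.0437 to 0.205), Fabp4 at 15.3 CPM (1.94 to 5.37) and Pparg at 64.5 CPM (45.9 to 50.3). EV day 2 replicate 4 held Fabp4 at 194 CPM (37.3 to 84.6), and EV day 4 replicate 2 held Adipoq at 67.4 CPM (0.834 to 15.8). P day 2 replicate 5 held Adipoq at 1022 CPM (27.0 to 349), and P day 4 replicate 5 held Pparg at 370 CPM (202 to 236). EV day 0 replicate 2 held Jmjd1c at 205 CPM (179 to 184), and PY day 0 replicate 3 held Cidea at 0.278 CPM (0.0483 to 0.134). Ppargc1a was 5.42 CPM in EV day 0 replicate 3 (others 0.0512 to 1.02) and 6.06 CPM in P day 0 replicate 2 (0.0503 to 1.6), both from experiment 3. Total counts were 71.09 M in EV day 2 replicate 1 (others 11.3 to 22.5), 114.6 M in P day 0 replicate 1 (18.8 to 42.5), 62.2 M in PY day 0 replicate 1 (4.12 to 25.1) and 6.969 M in PY day 4 replicate 2 (21.2 to 26.8).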

How the results depend on the processing

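The block of experiment and day and the removal of the 2 libraries with the lowest totals were chosen only after the data were seen; the other settings were fixed before. RLE size factors and the stricter filter kept all 18 counts within 1.5 times; DESeq2 did for 15, no filter for 13, the compared groups alone for 13, the experiment block for 8 and leaving out the 2 small libraries for 17. Where a count moved, the cause was not tested. The experiment block gave 24 genes for PY with EV at day 0, 4 for PY with P at day 2, 941 and 1717 for P with EV at days 2 and 4, 1739 and 2679 for PY with EV on those days, 3714, 4847 and 6031 for day 2 with day 0 in EV, P and PY, and 207 for the P to EV change. It changed no other count by more than 1.5 times. Experiment and day as the block gave 19, 24 and 196 genes at day 0 (PY with P, P with EV, PY with EV), 6, 2798 and 4054 at day 2, 5, 4088 and 5404 at day 4, and 1139 for the P to EV change. No filter gave 8 and 1 genes for PY with P at days 0 and 2, 537 and 1435 for day 2 with day 0 in EV and P, and 24 for the P to EV change. The compared groups alone gave 0 and 1 for PY with P at days 0 and 2, 1 for PY with EV at day 0, 1548 for day 2 with day 0 in P, and 158 for the P to EV change. DESeq2 gave 4 for P with EV and 21 for PY with EV at day 0, and 190 for the P to EV change, for which leaving out the 2 small libraries gave 79.

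Leaving out a library or an experiment gave ranges of 2 to 6 genes for PY with P at day 0, 1 to 3 at day 2, 5 to 12 for PY with EV at day 0, 171 to 566 for P with EV at day 2, 339 to 958 for PY with EV at day 2, 534 to 1103 for P with EV at day 4, 394 to 1657, 789 to 2980 and 1952 to 4261 for day 2 with day 0 in EV, P and PY, 3161 to 5633 for day 4 with day 0 in EV, and 0 to 129 for the P to EV change. Fewer samples and experiments lower the power, and the low ends mostly leave out experiment 1, 2 or 5.

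Of 162 gene results that passed, counted over comparisons, no filter lost 23, the compared groups alone 27, leaving out the 2 small libraries 2, and leaving out experiments 1 to 6 in turn 32, 32, 16, 11, 41 (of 160) and 26. RLE, the stricter filter (of 160), DESeq2 (of 161) and the experiment block lost 0, as did the block of experiment and day (of 113). Of 25 gene results that did not pass, 4 passed with the experiment block, 8 with the block of experiment and day and 2 in DESeq2, as did 1 of 23 with the stricter filter and 1 of 25 without experiment 1. Differences near 0 changed sign. In log2, Pparg in PY against P at day 2 was 0.01217 with RLE, 0.007542 with the stricter filter, 0.005405 with the experiment block, 0.07752 without the 2 small libraries and 0.01182 in DESeq2, and -0.0884 to 0.1023 as experiments were left out. Pink1 in PY against P at day 4 was 0.002038 with RLE, 0.005104 without the 2 small libraries and 0.002253 in DESeq2, and -0.05696 to 0.06868 as experiments were left out. Ybx1 in P against EV at day 0 was -0.04374 with the experiment block and -0.05759 with the block of experiment and day, and -0.001852 to 0.06287 as experiments were left out; at day 4 it was -0.0204 to 0.04177.

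Of 141 camera calls at the preset correlation, 24 held with an estimated correlation, 129 with the experiment block and 140 with RLE. Ucp1 had at most 10 counts in any library and was not tested.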

Other observations

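The test of a larger Pparg-guide response in PY was chosen only after the result was seen, while the splits were planned before the data were examined.

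Ppargc1a, a coactivator of mitochondrial and thermogenic genes, followed the experiment and not the guide. At day 4 it was 38.2, 38.1 and 35.5 CPM in EV, P and PY of experiment 2 and 29.5, 29.3 and 27.6 CPM in experiment 3, against at most 2.81 CPM in the other 4 experiments. The share of counts from mitochondrially encoded messenger RNAs at day 0 and day 4 was 0.469% ± 0.0356 (SD, n = 5) and 0.757% ± 0.373 (n = 6) in EV, 0.505% ± 0.0568 (n = 5) and 1.25% ± 0.716 (n = 6) in P, and 0.460% ± 0.0999 and 1.31% ± 0.766 (n = 6 each) in PY. Of the 13 such genes in the counts only 7 were kept by the low-count filter. How reads that map to several places were counted is not stated, so the share may not reflect their true level. In experiment 1 the share was lower at day 4 than at day 0, with 0.280% against 0.511% in EV, 0.371% against 0.484% in P and 0.366% against 0.472% in PY. In experiment 4 it was also lower at day 4 in EV (0.3995% against 0.438%), but not in P or PY. Among PY libraries of day 4, replicate 4 held Adipoq at 78.3 CPM and the others 658 to 1833 CPM.

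Ifit1bl1, an interferon-induced gene chosen after its values were seen, was higher in PY than in P at day 0 in 5 of 5 experiments (706 against 51.8 CPM in experiment 1, 349 against 223 CPM in experiment 6), with log2 1.79 and adjusted p = 1.

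Some genes that start within 250 kb of the guide targets were taken as values. Near Ybx1, log2 differences between PY and P at day 0 ran from -0.05 for P3h1 to 0.49 for Ccdc30, with 0.41 for Cldn19, 0.20 for Svbp and 0.30 for Gm37817, which starts 0.857 kb from Ybx1 (adjusted p = 1 each). Ccdc30 differed by 0.39 at day 2 and 0.40 at day 4 (adjusted p = 1 each). Near Pparg, Mkrn2 had a log2 difference between P and EV at day 0 of -0.05 (adjusted p = 1). Syn2 differed by 0.45 at day 0 (adjusted p = 1), 0.62 at day 2 (adjusted p = 0.861) and 1.93 at day 4 (adjusted p = 0.00714), and Gm44079, on the strand opposite to Pparg and so uncertain, by 2.54 at day 0 (adjusted p = 1), 2.94 at day 2 (adjusted p = 0.0022) and 0.90 at day 4 (adjusted p = 0.594).

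A hypothesis was that the Ybx1 guide enlarges the response to the Pparg guide, so that PY minus P rises with the P minus EV change. For each experiment the slope was taken over genes that differed between P and EV on the other day, which are not independent replicates. At day 2 the mean slope over 5 experiments was 0.0151 ± 0.139 (SD), positive in 3, with an exact two-sided sign-flip p of 0.688, where 0.0625 is the smallest possible. At day 4 it was 0.047 ± 0.173 over 6 experiments, positive in 5, with an exact p of 0.531 and a smallest possible of 0.0312. Leaving out 1 experiment moved the mean to between -0.0348 (without experiment 6) and 0.0609 (without experiment 1) at day 2. At day 4 it moved to between 0.0105 (without experiment 6) and 0.110 (without experiment 4). The slope of experiment 4 was -0.268, taken between replicate 4 of PY and replicate 4 of P. Without that experiment 5 of 5 slopes were positive, with an exact sign-flip p of 0.0625, the smallest possible there. With means that depend on 1 experiment, a small enlargement and none cannot be told apart.

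Each count was set against 100 splits of its libraries, the real one included. The rule fixed beforehand took a share of splits under 0.05 as arguing against chance, with no adjustment over the 18 comparisons. Part of the splits only exchanged libraries within experiments, so the share is not an exact p-value and cannot exclude chance. It was under 0.05 for PY with EV at day 0, where 3 splits gave as many as the real 8 genes, Ybx1 and Pparg among them (highest other 1261). So it was at day 2 with 1 split (806, highest other 538) and at day 4 with 1 (1333, highest other 1200). The share was also under 0.05 for P with EV at day 2 with 1 split (481, highest other 282) and at day 4 with 3 (914, highest other 1590). The same held for day 2 with day 0, with 1 split each, in EV (1244, highest other 1047), P (2383, highest other 954) and PY (3867, highest other 2868), and for day 4 with day 0, with 1 split each, in EV (5099, highest other 2812), P (6324, highest other 4303) and PY (6380, highest other 4102). For the P to EV change from day 0 to day 4, 2 splits gave as many as 52 genes (highest other 55).

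Over all 100 splits, chance could not be excluded for counts of PY with P: 8 splits gave as many as the 5 genes of day 0 (highest other 256), 5 as many as the 2 of day 2 (highest other 234) and 7 as many as the 3 of day 4 (highest other 1694). Nor could it over all splits for P with EV at day 0, where 10 splits gave as many as 1 gene (highest other 2247). With a real count of 0, all 100 splits gave as many for the PY to P change to day 2 (highest other 89) and to day 4 (highest other 70). Splits that call many times the real number point to a structure of the samples, since these part fewer of the experiment pairs than the labels do. Of the 32 splits that part as many pairs as the labels, 2 gave as many for PY with P at day 0 (highest other 5). These 32 include the split that reverses every pair, which is the same comparison backwards apart from the 1 unpaired library. They therefore cannot decide about chance there. At days 2 and 4 the real split alone gave as many among splits parting as many pairs (highest other 1 each). However, the 2 and 3 genes are Ybx1 and its copies, and the rule fixed beforehand counts all 100 splits. For P with EV at day 0 the 16 such splits are too few for a share under 0.05 (real 1, highest other 0). Among such splits the highest other was 4 for PY with EV at day 0, 512 for P with EV at day 4 and 1026 for PY with EV at day 4. For day 2 with day 0 in PY it was 2868 (real 3867). For the P to EV change it was 55, above the real 52, and 2 of 50 such splits gave as many, the real one included. Splits that mirror the labels were not screened out of these 50, so this share is only approximate.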
